A study of Homo sapiens with 12 samples.

How the data were processed

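Total RNA of HCT116 cells was measured in 12 libraries, and the labels put 4 in a DASHed and 4 in an untreated single-cell group, and 2 in a DASHed and 2 in an untreated mini-bulk group. Per the labels' protocols, single cells were sorted by FACS, and lysis, RNA extraction and library construction followed MATQ-seq for both inputs. The authors deposited 1 table of estimated counts per gene, not scaled to depth, in which 31.2 to 55.9% of the nonzero values of a library are fractional. The estimates were made with kallisto 0.46.2, per the submitters' processing notes. The genome build, the transcript annotation, the handling of strand and the way transcripts were summed to genes are not given in the sources used here. kallisto shares the reads that several transcripts could have produced among those transcripts, so values of near-identical sequences depend on each other. Named genes with near-identical or readthrough copies, antisense genes, and named genes that share at least 10% of their exonic bases with other genes on either strand (GENCODE v29) are called uncertain in the results.

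The table has 57134 genes, of which 57130 match gene names of GENCODE v29 (GRCh38), after 51 of 52 names that a spreadsheet appears to have damaged were restored. GENCODE v29 supplied coordinates and the median GC content and length of each gene's transcripts. The RefSeq table (GRCh38.p14) was used only for names and for which genes lie within which. Among the names, 219 belong to more than 1 GENCODE identifier, and for these no coordinate is given. No count was seen in any library for 26167 genes. The 7SK RNA reads stand under RF00100, a family name that covers several loci, and RN7SK itself is 0 throughout. Estimated counts were rounded to whole numbers before any test. A count of 3 was used as the floor for genes with no counts, which corresponds to 0.498 to 3.58 CPM (counts scaled to a common library total) in a library, depending on its total.

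Lists of genes, tests, samples, covariates and the rule for named genes were fixed before the data were examined. rRNA was the sum of 536 genes and pseudogenes of 18S, 28S, 5.8S, 5S and mitochondrial rRNA, of which 67 had counts. Shares and numbers of detected genes were compared in mini-bulk with an exact two-sided permutation test, whose smallest p with 2 against 2 libraries is 0.333. For detected genes the libraries of an input were thinned at random to the smallest total. Single cells carried no test, because each sample is 1 cell and no culture is named. They are given as values per cell, as shares of summed counts with exact (Clopper-Pearson) binomial 95% intervals and as ratios with exact Poisson-based intervals, which cover counting error only.

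Mini-bulk genes were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM factors, the default expression filter and Benjamini-Hochberg adjustment at 0.05. TMM factors were 1.96 and 2.09 for DASHed and 0.442 and 0.553 for untreated libraries. Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation, under which no list passed. The alternative fry, which asks whether the genes of a list move one way, was also run. For single cells the log2 ratio of summed CPM with a pseudocount of 1 CPM was taken over 13509 genes with at least 20 counts, minus the median of all genes. A list's median was placed among 10000 random lists drawn from the 200 genes nearest in expression to each member. The median of all genes rises with expression, so an alternative that sets each gene against the 301 genes around it in expression was added after the data were seen. Folds of named single-cell genes are relative to the median of all genes, 2.20-fold. Correlations of fold changes used genes with at least 100 counts in each input.

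The rule for named genes took every rRNA gene with at least 10 counts on average and the 12 genes with the largest fold each way among those past the threshold with both DASHed libraries on the same side of both untreated ones. From each list it took up to 3 members of largest fold past the threshold, or the 2 with the highest expression if none passed. In single cells it took the 10 genes with the largest ratio of medians each way among those with at least 10 counts in 3 of 4 cells of the higher group, and the same list members. A gene that the rule took is not reported here.

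The groups share replicate numbers, and the labels do not say what a number marks. Deviations from group means correlated at 0.92 to 0.93 between DASHed and untreated single cells of the same number, and at −0.38 to −0.22 between cells of different numbers, over 7751 genes. The negative values add no evidence, because centring on group means forces them where same-numbered cells correlate. The numbers were therefore taken to pair the single cells, from the data alone, and paired values are given where they change a direction. Leaving out a single cell breaks a pair. A gene with no counts in either cell of a pair has a ratio of 0 there, which lowers the all-gene median of the pair, so an alternative without such genes was added after the data were seen. Alternatives covered DESeq2 1.42.0 size factors and its Wald test, scaling to totals alone, removal of rRNA before scaling, other filters and pseudocounts, a test against 1.5-fold (glmTreat), replicate blocks, single-cell sums as further libraries, and each replicate left out in turn. Chosen after the data were seen were the removal or addition of the lincRNA genes inside 18S rRNA, the correction for GC content (a loess fit with span 0.5 per mini-bulk library, a running median in single cells) and the reference to genes of like expression.

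The steps were tested on simulated data. For the mini-bulk comparison, with 8760 genes, 11.5% of genes with a planted 2-fold and 47.7% with a planted 4-fold change were recovered, and 5.5% of calls were false. All simulated mini-bulk libraries had 1 pooled composition. The lower rRNA share of the real DASHed libraries was not simulated, so these rates may not hold for the real comparison of 10083 genes. A simulated GC trend gave 1503 false calls before and 8 after the correction. For single-cell lists, over 13506 genes, 4% of 200 lists without a planted change lay outside 95% of random lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.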

Results

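The series holds 12 total RNA libraries from HCT116, a human colon carcinoma cell line. All were made with MATQ-seq, an amplification protocol for total RNA that also captures transcripts without a poly(A) tail. The design compared libraries with and without scDASH, a depletion step in which Cas9 cuts sequence derived from ribosomal RNA (rRNA). Single cells, which were sorted by FACS, gave 4 DASHed and 4 untreated libraries. Mini-bulk input gave 2 DASHed and 2 untreated libraries. The deposited values are estimated counts per gene. Their totals were 837614 and 1087711 in the DASHed mini-bulk libraries and 5803180 and 6026584 in the untreated ones. The totals of the DASHed single cells were 1018874 to 1573651, and those of the untreated cells 5545355 to 6008358. The labels name no separate cultures, so p-values from the mini-bulk libraries measure only the spread between these samples, which may be technical. Each single-cell library is of 1 cell, so a single-cell group counts as 1 sample and carries no test. DASHed and untreated cells of the same number deviated from their group means together (correlation 0.92 to 0.93). The labels do not say whether such libraries came from the same cell, so the 2 groups may not hold different cells. Intervals and floors cover counting error only.

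The first question was how far the share of rRNA was lower after depletion. A share also depends on the counts of the other RNAs, so its ratio does not measure the amount removed. In the mini-bulk libraries rRNA, nuclear and mitochondrial together, took 22.96% ± 1.61 (SD, n = 2) of the counts after depletion and 46.9% ± 2.29 (SD, n = 2) without it, a ratio of 0.49. The values of the treated and untreated libraries did not overlap, and the exact two-sided permutation test gave p = 0.333, the smallest value that 2 against 2 libraries allow. The single cells held 20.5 to 24.4% rRNA after depletion and 49.5 to 52.9% without it, a ratio of means of 0.418. The summed cells gave 21.6% (exact binomial 95% interval 21.52 to 21.59%) against 51.6% (51.58 to 51.62%).

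The rRNA species differed in how far their shares were lower. 18S rRNA (RNA18S4), the small-subunit RNA, took 11.1% ± 1.0 of mini-bulk counts after depletion against 22.5% ± 1.29 without it. 28S rRNA (RNA28S4), the large-subunit RNA, took 5.10% ± 0.68 against 14.0% ± 1.81 (SD, n = 2 each). The ratios of treated to untreated share were 0.494 and 0.365 in mini-bulk, and 0.436 and 0.302 in single cells. Of the mitochondrial rRNAs, 16S rRNA (MT-RNR2) had ratios of 0.502 and 0.69 in the respective inputs, whereas 12S rRNA (MT-RNR1) had ratios of 0.90 and 1.003. The exact permutation p was 0.333 for 18S, 28S and 16S rRNA and 0.667 for 12S rRNA. 5.8S rRNA (RNA5-8S4) was scarce, at 0.0051% of mini-bulk counts after depletion against 0.00107%, a ratio of 4.75, and 0.0392% against 0.011% in single cells, a ratio of 3.55. 5S rRNA took under 0.001% of counts in each group mean, with ratios of 1.35 in mini-bulk and 2.03 in single cells. Against other genes, on the TMM scale, the mini-bulk differences were larger than those in share. There 18S rRNA was 8.27-fold, 28S rRNA 11.2-fold, 16S rRNA 8.09-fold and 12S rRNA 4.50-fold lower, while 5.8S rRNA was 1.16-fold higher and did not pass the threshold.

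A further 37.1% of the untreated mini-bulk counts lay in 4 genes annotated as long intergenic non-coding RNA (lincRNA) whose GENCODE v29 transcripts sit inside 18S rRNA genes on the minus strand of chromosome 21 (GRCh38). These were FP671120.3 (8210384 to 8211306), FP671120.4 (8254592 to 8255514), FP236383.2 (8393419 to 8394341) and FP236383.3 (8437629 to 8438551). The transcripts of FP236383.2, FP236383.3 and FP671120.3 are identical, and FP671120.4 shares 93.2% of its 31-base words with them. The RefSeq table (GRCh38.p14) places them, in the order of their positions, within RNA18SN2, RNA18SP5, RNA18SN3 and RNA18SN1. Their values are uncertain as levels of separate genes. Their joint share was 17.4% ± 1.70 in DASHed and 37.1% ± 0.30 (SD, n = 2 each) in untreated mini-bulk libraries, and 11.99% against 26.3% in single cells. With these genes added, an alternative chosen after the data were seen, rRNA took 40.4% against 84.0% of mini-bulk counts and 33.6% against 77.8% of single-cell counts.

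**Figure D1:**
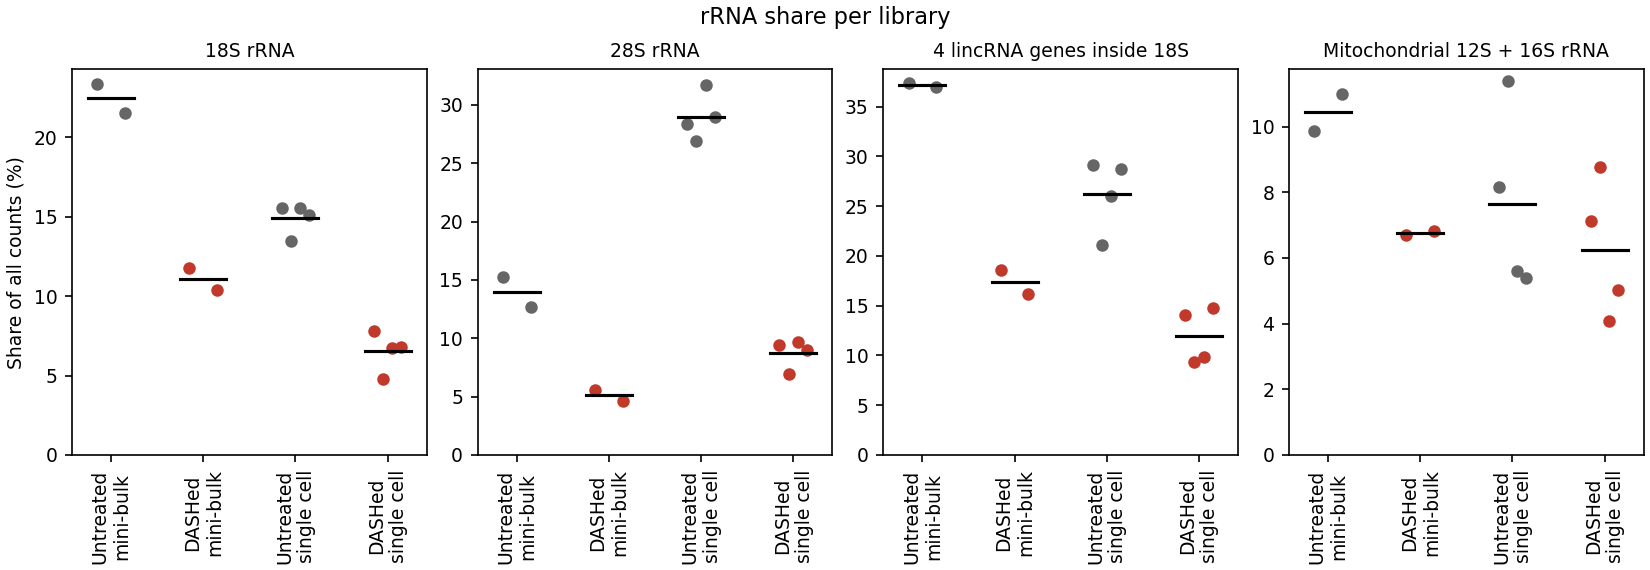
Share of all counts (percent, y axis) in 18S rRNA, 28S rRNA, the 4 lincRNA genes inside 18S rRNA and the mitochondrial rRNAs (panels) for the 4 groups, with 1 point per library and a line at each group mean. In the first 3 panels every DASHed library lay below every untreated library of its input, and in the mitochondrial panel the single cells overlapped, at 4.09 to 8.78% against 5.38 to 11.4%, although each DASHed cell lay below the untreated cell of the same number (ratios 0.73 to 0.93).

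Most other RNA classes took larger shares after depletion, while those encoded in mitochondria took smaller ones. The mini-bulk share of mRNAs of cytosolic ribosomal proteins was 1.09% ± 0.087 against 0.207% ± 0.0046, a ratio of 5.27, and that of replication-dependent histone mRNAs was 0.421% ± 0.003 against 0.046% ± 0.0068, a ratio of 9.16 (SD, n = 2 each). Ratios in single cells were 3.78 and 6.08. The histone ratio was 4.59 to 6.35 within the same-numbered pairs, while leaving out a single cell of the histone-rich pair 1 moved it to 1.66 without DASHed replicate 1 and 19.1 without untreated replicate 1. Small structured RNAs, the group of the signal recognition particle, RNase P and Y RNAs, had ratios of 8.32 and 5.17. Small nucleolar and Cajal body RNAs had 3.47 and 1.997, and nuclear long non-coding RNAs 1.45 and 1.32. Spliceosomal small nuclear RNAs had 1.98 in mini-bulk and 0.866 in single cells, where the mean ratio over same-numbered pairs was 1.03. Left-out cells, which break a pair, turned it too, to 1.05 without DASHed replicate 1 and 1.04 without untreated replicate 4. The 13 mitochondrial mRNAs took 1.18% ± 0.092 against 1.72% ± 0.294 in mini-bulk, a ratio of 0.685, and 1.11% against 1.62% in single cells, a ratio of 0.682. Mitochondrial tRNAs had ratios of 0.23 and 0.474. Each of these mini-bulk differences had an exact permutation p of 0.333, the smallest possible.

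The second question was whether more genes were seen at a given depth. With every mini-bulk library thinned to 837450 counts, 16063 ± 236 genes had at least 1 count after depletion and 13687 ± 510 without it (SD, n = 2 each), a ratio of 1.17 with an exact permutation p of 0.333. At a minimum of 10 counts the numbers were 6568 ± 70 and 3028 ± 449, a ratio of 2.17. Single cells, thinned to 1018815 counts, had 9897 to 12181 genes after depletion and 9936 to 11525 without it, ranges that overlapped, with a ratio of 1.04. In the order of their numbers, same-numbered cells had 11498 against 10950, 9897 against 9936, 12181 against 11525 and 11960 against 11494 genes. At a minimum of 10 counts the cells held 5133 to 6401 and 4203 to 4607 genes, a ratio of 1.32. Without thinning the direction turned, because the untreated libraries were deeper, with ratios of 0.759 in mini-bulk and 0.783 in single cells. With rRNA left out before thinning, the mini-bulk ratio was 1.06 and the single-cell ratio 0.935. Each DASHed cell then lay below the untreated cell of the same number. The lincRNA genes inside 18S rRNA stayed in, so depth over the other genes was still unequal. Their share of all counts was 37.1% in untreated against 17.4% in DASHed mini-bulk libraries, and 26.3% against 11.99% in single cells.

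**Figure D2:**
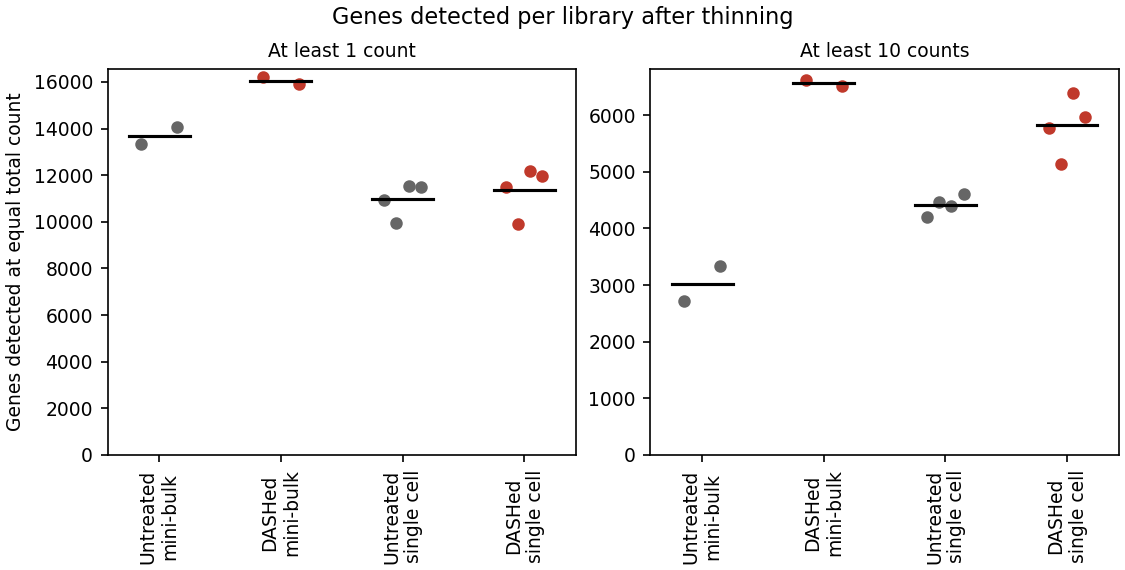
Genes detected per library after thinning to equal totals within each input (y axis, number of genes), at the minimum counts marked on the panels, with 1 point per library and a line at each group mean. At a minimum of 10 counts every DASHed library lay above every untreated library of its input.

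The third question was which transcripts changed against the rest of the transcriptome. Of 10083 genes tested in the mini-bulk libraries, 998 rose and 1999 fell at an edgeR adjusted p of 0.05. The fold changes are on the TMM scale, on which the median log2 fold change of all tested genes was 0.032. Scaling to total counts alone moved that median to 2.04 and turned the split from 33.3% to 98% higher, with 6718 genes up and 138 down. Genes that fell by less than this shift on the TMM scale therefore took a larger share of counts after depletion. Without untreated replicate 1 there were 1417 calls (225 up, 1192 down) and without untreated replicate 2 there were 1426 (205 up, 1221 down), so the rises depended more on these libraries than the falls. Fold changes followed the GC content of the transcripts, with Spearman's rho = 0.789 across 10080 genes, which are not independent replicates. For the median length of a gene's annotated transcripts, which need not be the expressed length, rho was −0.03. Genes that rose had a median GC content of 59.3%, those that fell 42.7%, and all tested genes 51.4%. With a correction for GC content, chosen after the data were seen, 174 genes rose and 221 fell, and 274 of these 395 were among the 2997 earlier calls, 269 of them in the same direction.

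**Figure D3:**
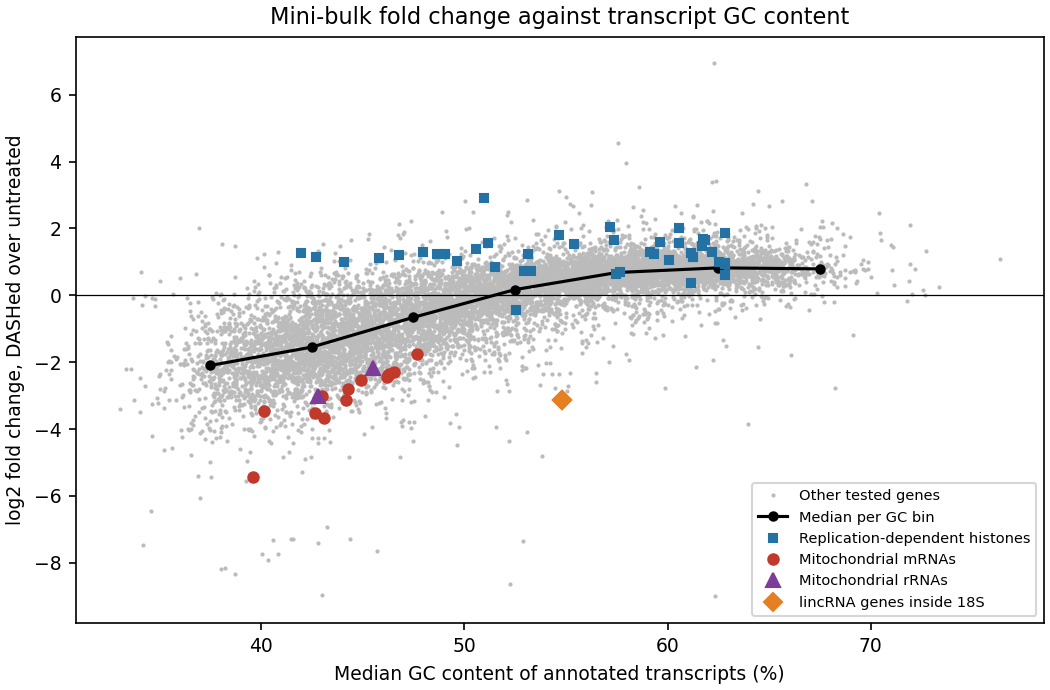
Log2 fold change of DASHed over untreated mini-bulk libraries (y axis) against the median GC content of each gene's transcripts (percent, x axis), with 1 point per tested gene and black points at the medians of GC bins. The medians went from −2.10 at 35 to 40% GC to 0.82 at 60 to 65% GC, and mitochondrial mRNAs lay below the medians of their bins.

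Among named mini-bulk genes, 18S rRNA fell by 3.05 on the log2 scale (SE 0.22, edgeR adjusted p = 5.49e-05) and 28S rRNA by 3.49 (SE 0.25, 5.14e-05), while 5.8S rRNA had a log2 fold change of 0.22 (SE 0.30, 0.597). The 12 largest falls were of genes with no count in either DASHed library, so their folds are bounds against a floor of 3 counts over the group. They include CCNG1, which encodes cyclin G1 (at least 19-fold lower), KIF20B, which encodes a kinesin of cell division (at least 11.6-fold), ADAM32 (at least 14.0-fold) and RSC1A1 (at least 10.9-fold). LINC02503, AC005899.4, AC021097.2 and AC022929.2 were at least 16.2-fold to 25.5-fold lower. AC007192.1 (at least 33.6-fold lower) and IFI30, which encodes a lysosomal thiol reductase, share a stretch of chromosome 19 that ends at 18178117 (GENCODE v29). IFI30 rose, with 50 counts against 3, a ratio of 25.5 (counting interval 8.22 to 128), and both values are uncertain. Further large rises were those of KLF2, a transcription factor gene (22 against 3 counts, ratio 11.2, 3.36 to 58.4), PSCA, which encodes a cell surface protein (23 against 3, ratio 11.7, 3.54 to 60.9), AC008894.2 (57 against 10, ratio 8.71), LINC02108 (22 against 4, ratio 8.4), AL138724.1 (16 against 2, ratio 12.2, 2.87 to 110) and AC025257.1 (13 against 2, ratio 9.93, 2.25 to 90.6). AC112777.1 was at least 12.2-fold higher. After GC correction some of these calls ended although the folds stayed large. The log2 fold change went from 3.33 (SE 0.81) to 2.57 (SE 0.86, edgeR adjusted p = 0.153) for KLF2, from 3.38 (SE 0.91) to 2.68 (SE 0.95, 0.18) for PSCA, from 2.95 (SE 0.78) to 2.55 (SE 0.79, 0.121) for LINC02108, from 3.41 to 2.69 for AL138724.1, from 3.12 to 2.77 for AC025257.1, from 3.13 to 2.40 for KRT87P, from 3.25 to 2.63 for KRTAP2-5P and from 3.96 to 3.36 for NDUFC2-KCTD14. KIF20B (0.118) and RSC1A1 (0.0518), with no counts after depletion, also missed the threshold. Uncertain because of near-identical or readthrough copies are RPL9P9, AC112777.1, KRT87P, KRTAP2-5P, NDUFC2-KCTD14 and HIST2H4B, and because of exons shared with other genes on the same or the opposite strand RSC1A1, PSCA, LIMD1-AS1, AC005899.4, AC021097.2, AC008894.2, AC025257.1 and AL138724.1.

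Mitochondrially encoded transcripts fell together. All 13 mitochondrial mRNAs, which encode subunits of the respiratory chain and ATP synthase, fell, with a median log2 fold change of −2.81 (camera adjusted p = 6.58e-09; adjusted p = 0.544 with an estimated correlation) and a median GC content of 44.3%. MT-ATP8, which shares exonic bases with MT-ATP6 and so is uncertain, fell by 5.45 (SE 0.38, edgeR adjusted p = 4.80e-05), MT-ND4L fell by 3.67 (SE 0.17, 2.19e-05) and MT-ND6 fell by 3.52 (SE 0.21, 3.12e-05). The mitochondrial lists had the same counts adjusted over the list alone. After the GC correction all 13 mRNAs still fell, with a median of −1.63. Both mitochondrial rRNAs fell, with MT-RNR1 at −2.17 (SE 0.15) and MT-RNR2 at −3.02 (SE 0.17), for a list median of −2.59 and a median GC content of 44.1% (camera adjusted p = 0.0347; adjusted p = 0.572 with an estimated correlation). That call ended without DASHed replicate 1 (camera adjusted p = 0.0928) and without DASHed replicate 2 (0.0603). Replicate number as a block ended the mitochondrial rRNA call too. All 7 tested mitochondrial tRNAs fell, with a median of −3.94, or −3.39 with MT-TL1 at its bound, and a median GC content of 42% (camera adjusted p = 0.000106, and 0.544 with an estimated correlation). MT-TV fell by 5.34 (SE 0.47, edgeR adjusted p = 0.000129), and MT-TL1 was at least 10.5-fold lower. After the GC correction the tRNA list still passed with a median of −2.72 (camera adjusted p = 3.63e-06), but only 1 of the 7 genes, MT-TV, was past the threshold. Of nuclear copies of 16S rRNA sequence, MTRNR2L1 fell by 4.85 (SE 0.24) and MTRNR2L12 fell by 4.42 (SE 0.53), and their near-identity to mitochondrial sequence makes these values uncertain. The list of rRNA-like nuclear genes to which they belong had 2 members up and 3 down of 6, or 3 and 3 adjusted over the list alone, with a median of −1.28 and a median GC content of 43.5% (camera adjusted p = 0.647). The 3 nuclear rRNAs had a median of −3.05 with 2 of 3 down (camera adjusted p = 0.151), and after GC correction of the other genes this was 0.0178.

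The mRNAs of replication-dependent histones, the proteins that package newly made DNA, end mostly without poly(A), and they rose. Of 42 tested, 24 rose and none fell, or 27 adjusted over the list alone, with a median log2 fold change of 1.25 (camera adjusted p = 5.09e-11; adjusted p = 0.544 with an estimated correlation) and a median GC content of 57.4%. HIST2H2AC rose by 1.85 (SE 0.22, edgeR adjusted p = 0.000659) and HIST4H4 by 1.79 (SE 0.58, 0.0438). After GC correction the list median was 0.90 (camera adjusted p = 3.77e-10), and 15 members rose, with HIST2H2AC at 1.07 (edgeR adjusted p = 0.0195), while HIST4H4 at 1.42 (0.246) did not pass. Immediate-early and heat shock genes had 5 members up and 1 down of 18, the same numbers adjusted over the list alone, with a median of 0.65 and a median GC content of 58.5% (camera adjusted p = 0.019; adjusted p = 0.544 with an estimated correlation). IER2 and JUNB, genes of the early transcriptional response, rose by 1.39 (SE 0.21) and 1.11 (SE 0.25), and both are uncertain because of genes on the opposite strand. HSPH1, which encodes a chaperone, fell by 2.42 (SE 0.18) with a GC content of 39.7%. The list median was 0.01 after GC correction (camera adjusted p = 0.962), where the folds of IER2, JUNB and HSPH1 shrank to 0.61, 0.30 and −0.62 and their calls ended. The list call also ended without untreated replicate 1 (0.0787), without untreated replicate 2 (0.103) and under scaling to total counts alone (0.1).

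Another 4 lists fell against other genes on the TMM scale, and the medians of all 4 lay above 0 under scaling to total counts alone. Chaperone and proteasome genes fell in 14 of 23 cases with none up, or 15 down and 1 up adjusted over the list alone, with a median of −1.18 and a median GC content of 45.5% (camera adjusted p = 0.000825; adjusted p = 0.585 with an estimated correlation). HSPD1 and HSPE1, the mitochondrial chaperonin pair, fell by 3.16 (SE 0.26) and 3.14 (SE 0.53), and HSPE1 is uncertain because its exons overlap those of HSPD1. G2 and M phase genes fell in 15 of 23 cases with 2 up, or 16 and 3 adjusted over the list alone, with a median of −1.30 and a median GC content of 44.8% (camera adjusted p = 0.00383; adjusted p = 0.572 with an estimated correlation). TOP2A, the DNA topoisomerase of dividing cells, fell by 3.33 (SE 0.32), KIF23 by 2.41 (SE 0.55) and ASPM by 2.40 (SE 0.49). Nuclear long non-coding RNAs fell in 7 of 10 cases, also adjusted over the list alone, with a median of −1.68 and a median GC content of 43.7% (camera adjusted p = 0.00256; adjusted p = 0.544 with an estimated correlation). TUG1 fell by 3.06 (SE 0.32, uncertain because of overlapping genes), MALAT1, a nuclear speckle RNA, by 2.33 (SE 0.19) and OIP5-AS1, an antisense gene and so uncertain, by 2.45 (SE 0.45). snoRNA host genes fell in 6 of 13 cases, also adjusted over the list alone, with a median of −1.41 and a median GC content of 45% (camera adjusted p = 0.0151; adjusted p = 0.544 with an estimated correlation). SNHG1 fell by 2.31 (SE 0.24), SNHG6 by 1.97 (SE 0.59) and ZFAS1, an antisense gene, by 2.46 (SE 0.49), and all 3 are uncertain because they share exonic bases with other genes. After GC correction none of these 4 lists passed, with camera adjusted p of 0.0764, 0.688, 0.123 and 0.604 in the order given. HSPD1 (−2.07), HSPE1 (−2.40), TOP2A (−1.42), TUG1 (−1.55), SNHG1 (−1.17) and ZFAS1 (−2.28) still passed with smaller folds, whereas the folds of KIF23 (−0.99), ASPM (−0.30), MALAT1 (−0.49), OIP5-AS1 (−1.61) and SNHG6 (−0.50) shrank and their calls ended. The snoRNA host call also ended without DASHed replicate 1 (camera adjusted p = 0.0689), without DASHed replicate 2 (0.10) and under scaling to total counts alone (0.148).

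Several lists that did not pass the camera test had members that rose and members that fell. Ribosomal protein genes had 18 up and 17 down of 79, or 25 and 21 adjusted over the list alone, with a median of 0.14 but a mean of −0.07 (median GC content 50.3%). RPL7 fell by 2.10 (SE 0.20, GC content 43.3%) and RPS24 by 2.09 (SE 0.41). Glycolytic enzymes had 8 up and 2 down of 18, with a median of 0.70 (median GC content 55.7%, camera adjusted p = 0.0601), where PFKP rose by 1.10 (SE 0.23) while LDHA fell by 2.88 (SE 0.18) and LDHB by 2.43 (SE 0.23, uncertain because of an overlapping gene), the last 2 encoding lactate dehydrogenase. Translation factors had 5 up and 12 down of 25, with a median of −0.82 (median GC content 48.7%, camera adjusted p = 0.151), and EIF4E, which encodes the cap-binding protein, fell by 3.90 (SE 0.39). Respiratory chain genes of the nucleus had 2 up and 6 down of 35 with a median of 0.52, where UQCRB fell by 2.28 (SE 0.44) and UQCRH by 2.26 (SE 0.26). Ribosome assembly factors had 6 up and 9 down of 27 with a median of −0.29, where NPM1, which encodes nucleophosmin, fell by 2.31 (SE 0.23) and DDX21, an RNA helicase gene, by 2.24 (SE 0.25). S phase genes had 4 up and 5 down of 25 with a median of −0.19, where HELLS fell by 2.20 (SE 0.37) and CLSPN by 2.13 (SE 0.30). Median GC contents of these 3 lists were 50.2, 48.4 and 50%. Targets of p53 had 1 up, CDKN1A by 0.93 (SE 0.25), and 1 down, MDM2 by 1.94 (SE 0.28), of 15, with a median of 0.41 (median GC content 57%). Reference genes had 5 up and 4 down of 16, with a median of 0.37 but a mean of −0.10, where YWHAZ fell by 2.85 (SE 0.18) and TFRC by 2.08 (SE 0.17) (median GC content 53.4%). Long coding genes had 7 up and 6 down of 20, with a median of 0.30 but a mean of −0.06 (median GC content 52.5%). Small structured RNAs had 3 up and 1 down of 5, with a median of 1.13 and a median GC content of 62.7%. RMRP and RPPH1, the RNAs of RNase MRP and RNase P, rose by 1.15 (SE 0.24) and 1.14 (SE 0.23, uncertain because it lies inside AL355075.4), and BCYRN1 fell by 2.16 (SE 0.61). None of 5 small nucleolar and Cajal body RNAs passed (median 0.28, median GC content 51.7%), nor did RNU2-1, the 1 tested small nuclear RNA, at 1.10 (SE 0.52). No 5S rRNA gene was tested. After GC correction LDHA (−1.88), LDHB (−1.23), EIF4E (−2.33), UQCRH (−1.52) and YWHAZ (−1.70) still passed. The folds of RPL7 (−0.78), RPS24 (−0.90), PFKP (0.47), UQCRB (−0.30), NPM1 (−0.79), DDX21 (−0.59), HELLS (−0.14), CLSPN (−0.86), CDKN1A (0.23), MDM2 (−0.31), TFRC (−0.53), RMRP (0.36) and RPPH1 (0.34) shrank and their calls ended, as did that of BCYRN1 at −2.34 (edgeR adjusted p = 0.0709). Adjusted over the list alone, the numbers up and down were 9 and 2 for glycolysis, 6 and 13 for translation factors, 2 and 5 for the nuclear respiratory chain, 7 and 11 for ribosome assembly, 4 and 6 for S phase, 6 and 4 for reference genes and 9 and 7 for long coding genes, and those of p53 targets and small structured RNAs did not move. With a library left out some of these lists passed. Without DASHed replicate 2 the camera adjusted p was 0.0211 for glycolysis and for colon epithelial genes, 0.0473 for the nuclear respiratory chain and 0.0464 for ribosomal proteins. For translation factors it was 0.0292 without untreated replicate 1 and 0.019 without untreated replicate 2. It was 0.0405 for small structured RNAs without untreated replicate 1 and 0.0222 for nuclear rRNAs without untreated replicate 2. Under scaling to total counts alone it was 0.0179 for nuclear rRNAs, 0.0188 for rRNA-like nuclear genes and 0.0365 for ribosomal proteins, and for glycolysis it was 0.0337 with rRNA and the lincRNA genes inside 18S rRNA removed.

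Marker lists described what the libraries held. Colon epithelial genes had 3 up and 1 down of 10, with a median of 0.66 and a median GC content of 58.2% (camera adjusted p = 0.17). The keratin genes KRT8 and KRT19 rose by 1.10 (SE 0.15) and 0.90 (SE 0.22), and EPCAM, an epithelial adhesion molecule gene, fell by 2.12 (SE 0.49, GC content 45.1%). After GC correction their folds shrank to 0.46, 0.19 and −1.08, and all 3 calls ended (edgeR adjusted p = 0.123, 0.736 and 0.331). The numbers were the same adjusted over the list alone. None of 3 fibroblast, 2 neural and 1 leukocyte genes tested passed, while 1 neural gene was down adjusted over the list alone. Their medians were 0.72, −0.42 and 0.55, the last being CD68 alone, which is uncertain because of an overlapping gene. No endothelial or erythroid marker was tested in mini-bulk, because none had enough counts. In single cells the medians relative to all genes were 0.61 for colon epithelial, 0.66 for fibroblast, −0.22 for neural, −0.63 for leukocyte and −1.35 for erythroid genes, all within 95% of random lists, and 1 endothelial gene was measured.

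In single cells, summed over the 4 cells of a group, the median of the log2 ratio over 13509 genes was 1.13, and values below are relative to it. The 13 mitochondrial mRNAs lay at a median of −2.08, below all 10000 random lists matched on expression (95% range 0.55 to 1.09), with a median GC content of 44.3%. MT-ATP8 (uncertain, as above) was 20.3-fold lower (counting interval 15.9 to 26.3) and MT-ND4L 8.19-fold (7.39 to 9.10). All 18 measured mitochondrial tRNAs were lower, with a median of −2.16 (percentile 0, median GC content 40%), MT-TV by 38.9-fold (21.6 to 78.1). The mitochondrial rRNAs (−1.46, percentile 0.87, median GC content 44.1%), the nuclear rRNAs (−2.31, percentile 0) and the rRNA-like nuclear genes (−1.95, percentile 0, median GC content 41.1%) also lay low. Histone mRNAs were at 1.31 (percentile 100, median GC content 59.2%), with 44 of 44 above the median of all genes. Cells of number 1 were rich in histone mRNA in both groups, with shares of 1.41% in the DASHed cell against 0.0904 to 0.147% in the others, and 0.222% in the untreated cell against 0.0162 to 0.0273%. Leaving out a single cell of this pair moved the list median to −1.35 without DASHed replicate 1 and 2.87 without untreated replicate 1, while after depletion the histone share was 4.59 to 6.35 times as high within the 4 pairs. The list medians of single pairs were −0.80 to 2.08, or 1.15 to 1.77 with genes that had no counts in either cell of a pair left out, an alternative chosen after the data were seen.

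Below their random lists were also chaperone and proteasome genes (−0.68, percentile 0, median GC content 45.5%), G2 and M phase genes (−0.63, percentile 0.01, median GC content 43.4%), nuclear long non-coding RNAs (−0.63, percentile 0.41, median GC content 43.7%) and translation factors (−0.11, percentile 0, median GC content 48.7%). With same-numbered cells paired, the G2 and M phase and translation factor medians turned to 0.01 and 0.54, and single pairs gave −0.08 to 0.25 for G2 and M phase genes and −0.13 to 0.10 for chaperone and proteasome genes. The all-gene median of a pair was 0.80 or less, since 1605 to 3002 genes had no counts in either cell. With those genes left out, single pairs gave −0.30 to 0.00 for G2 and M phase genes, −0.51 to −0.39 for chaperone and proteasome genes and 0.11 to 0.32 for translation factors. The translation factor median also lay above 0, at 0.004 to 0.114, when DASHed replicate 1, 2 or 3 or untreated replicate 2 or 4 was left out, which breaks a pair. The medians of ribosomal protein genes (0.60, percentile 0.29, median GC content 50.3%), ribosome assembly factors (0.17, percentile 0.51, median GC content 48.3%) and long coding genes (0.47, percentile 1.93, median GC content 52.5%) were above the median of all genes but low among random lists, since highly expressed genes had larger ratios. The ratio of all genes rose from 1.13 to 1.92 between minimums of 20 and 1000 counts. The other 10 lists of at least 2 genes outside the cell type markers lay within 95% of their random lists. Their medians were 1.002 for small structured RNAs, 0.92 for glycolysis, 0.91 for immediate-early genes, 0.67 for reference genes, 0.50 for p53 targets, 0.34 for nuclear respiratory chain genes, 0.29 for S phase genes, −0.22 for snoRNA hosts, −0.59 for small nucleolar and Cajal body RNAs and −1.89 for small nuclear RNAs. Only 1 gene of 5S rRNA was measured. After GC correction, still outside 95% of random lists on the same side were the mitochondrial mRNAs (−1.21, percentile 0), mitochondrial tRNAs (−1.22, percentile 0.04), histones (0.75, percentile 100), nuclear long non-coding RNAs (−0.25, percentile 1.06), translation factors (0.06, percentile 0.45) and chaperone and proteasome genes (−0.08, percentile 0.13). Ribosomal protein genes went from the bottom to the top of their random lists (0.38, percentile 99.82). Mitochondrial rRNAs (−0.76, percentile 5.11), rRNA-like nuclear genes (−0.73, percentile 3.6), G2 and M phase genes (0.08, percentile 17.62), ribosome assembly factors (0.12, percentile 9.85) and long coding genes (0.25, percentile 36.59) came to lie within that range, and small nucleolar and Cajal body RNAs below it (−0.91, percentile 1.11). The nuclear rRNAs have no GC content in the annotation and were not corrected. With GC correction and same-numbered cells paired, 6 lists lay outside 95% of random lists. The medians of nuclear long non-coding RNAs and of chaperone and proteasome genes then turned to 0.16 and 0.21, and that of translation factors was 0.47.

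**Figure D4:**
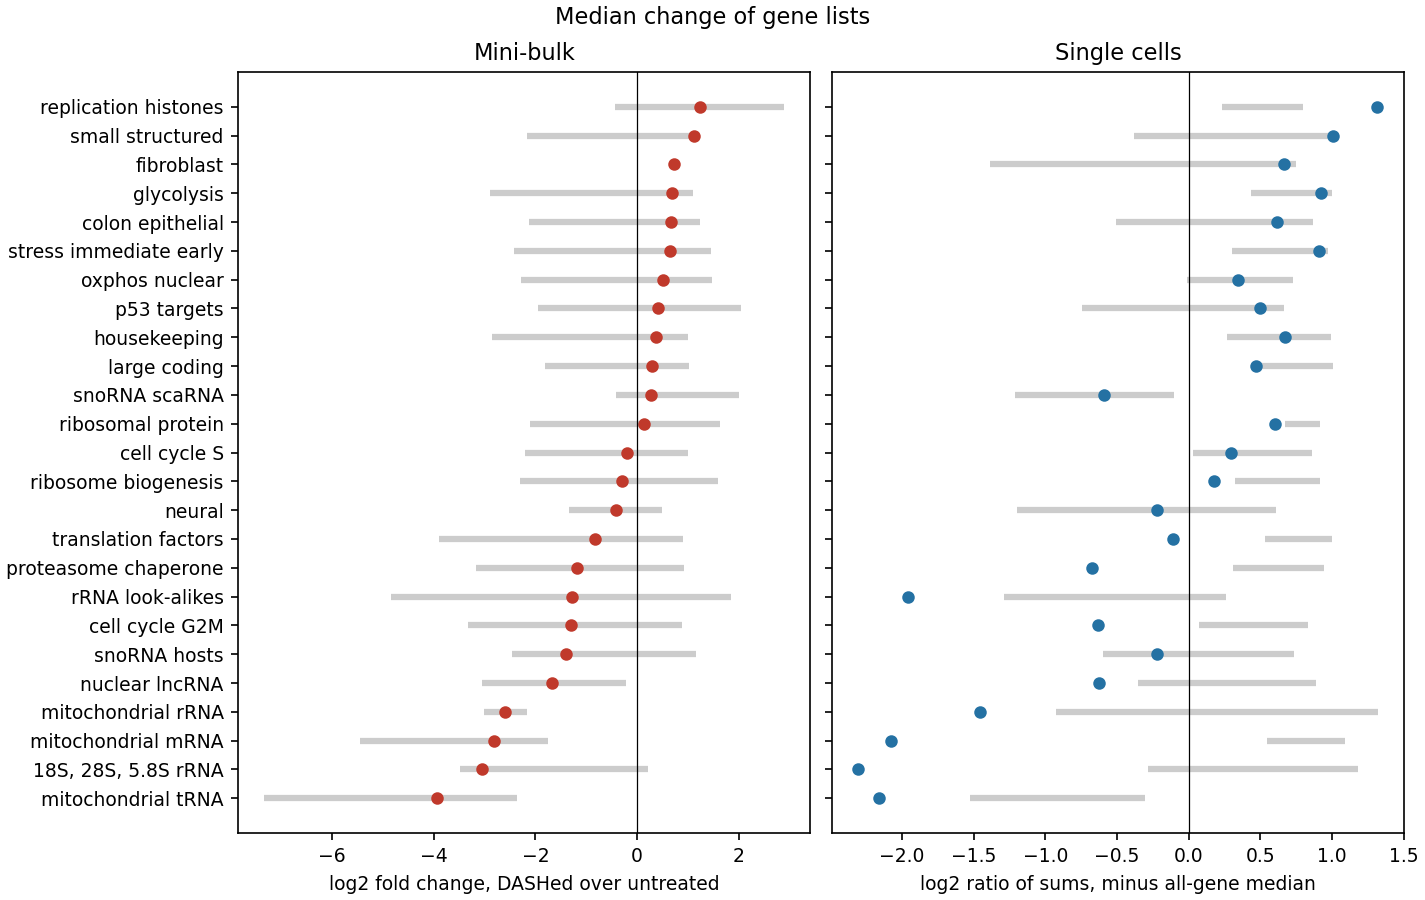
Median log2 fold change of each gene list (points) in mini-bulk, where grey bars span the members' range, and in summed single cells minus the median of all genes, where grey bars span 95% of random lists matched on expression. Histones lay highest in both panels, at 1.25 and 1.31, and the medians of the mitochondrial mRNAs were −2.81 and −2.08.

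The largest single-cell differences by size were of coding and non-coding genes. Of non-coding genes higher after depletion, LINC01551 was 40.7-fold higher (counting interval 16.9 to 128), AL390783.1 9.83-fold (7.19 to 13.7), AL355075.4 6.42-fold and LINC00273 5.51-fold. Of protein-coding genes, AL031777.3 was 7.26-fold higher, MRPL12, which encodes a mitochondrial ribosomal protein, 5.09-fold (4.19 to 6.21) and BCAN, which encodes the proteoglycan brevican, 4.06-fold (3.31 to 4.99). AL031777.3 shares exonic bases with the histone genes HIST1H3D and HIST1H2AD. Its log2 ratio was −0.07 to 3.46 over same-numbered pairs, with 1 of 4 pairs below the all-gene median. ANKRD30BL was 3.85-fold higher (3.70 to 4.00). Of those lower, AL662797.1 was 23.7-fold lower (16.7 to 35.1), LINC01609 17.6-fold (8.40 to 44.2), AL445685.3, with 3 against 196 counts, 34.1-fold (11.5 to 167) and AC007743.1, with 2 against 194, 50.6-fold (13.8 to 420). AC005899.4 and AC139530.2 had no counts in DASHed cells and were at least 41.9-fold and 34.1-fold lower against a floor of 3 counts over the group. Uncertain because of near-identical or readthrough copies are ZFP91-CNTF (at least 87.6-fold higher), HIST2H4B, RPL21P16 and RAC1P2, and because of exons shared with other genes on the same or the opposite strand AL390783.1, AL355075.4, AL031777.3, MRPL12, BCAN, AL662797.1, AL445685.3, AC007743.1, AC005899.4 and AC139530.2.

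The fold changes of both inputs, which share no libraries, were correlated across genes, which are not independent replicates (Pearson's r = 0.899, Spearman's rho = 0.877, 5290 genes with at least 100 counts in each input). The same side of the respective all-gene median was taken by 88.3% of these genes, and after GC correction r was 0.714. In single cells the log2 ratio followed GC content with rho = 0.696 over 13506 genes. Between libraries of 1 group, the mean correlation of log2 expression over 15651 genes was 0.895 for DASHed and 0.944 for untreated mini-bulk (1 pair each), but 0.891 and 0.839 once the libraries were thinned to equal totals, of which rRNA and the lincRNA genes inside 18S rRNA took 40.4% and 84.0%, so that depth over the other genes stayed unequal. It was 0.585 (0.552 to 0.621) for DASHed and 0.611 (0.573 to 0.648) for untreated single cells (6 pairs each).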

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

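Of 46 groups of 4 single cells examined for a value far from the others, 6 held one. Chance gives about 1 in 20 where groups are independent. These groups draw on the same cells, and same-numbered cells deviate together, so the 6 cannot be weighed against that rate. The rRNA share of DASHed single cell 1 was 24.4%, against 20.5 to 20.8% in the other 3 DASHed cells. The share of replication-dependent histone mRNAs was 1.41% in DASHed single cell 1, against 0.0904 to 0.147% in the others, and 0.222% in untreated single cell 1, against 0.0162 to 0.0273%. DASHed single cell 4 stood apart with a mitochondrial tRNA share of 0.0132% (others 0.00494 to 0.00599%), a ribosomal protein share of 2.81% (others 1.75 to 1.87%) and a nuclear long non-coding RNA share of 0.0806% (others 0.0463 to 0.0481%). Untreated single cell 4, of the same number, was also the highest of its group in mitochondrial tRNA, at 0.0233% against 0.0107 to 0.0149%, and in ribosomal protein mRNA, at 0.724% against 0.449 to 0.563%, but not in nuclear long non-coding RNA, at 0.0442% against 0.037 to 0.0449%.

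In 125 comparisons of the direction of a list or named gene relative to all genes, 4 had every same-numbered single-cell pair on the other side of 0 from every mini-bulk pair. The lists were taken over the members measured in both inputs. The difference between the inputs was not tested. Translation factors were 1.14 higher in single cells than in mini-bulk on the log2 scale (0.61 to 0.71 per pair of cells, −0.49 in mini-bulk). S phase genes were 1.02 higher (0.73 to 1.13 against −0.26 to −0.11), G2 and M phase genes 1.18 higher (0.05 to 0.30 against −1.14 to −0.92, but −0.08 to 0.25 over all members measured in single cells), and SNHG6 was 2.35 higher (0.01 to 1.38 against −2.19 to −1.34). Genes with no counts in either cell lower the all-gene median of a pair. Without them, an alternative chosen after the data were seen, pairs of cells gave 0.108 to 0.318 for translation factors and 0.178 to 0.793 for S phase genes, still opposite to mini-bulk, but −0.216 to 0.013 for G2 and M phase genes and −0.493 to 1.076 for SNHG6. Summed over cells, translation factors (−0.112), G2 and M phase genes (−0.413 over these members) and SNHG6 (−0.084) lay on the side of mini-bulk, and S phase genes (0.297) did not. With each gene set against genes of like expression, an alternative chosen after the data were seen, 0 of these comparisons went opposite ways.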

How the results depend on the processing

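The GC correction, the handling of the lincRNA genes inside 18S rRNA and the reference to genes of like expression were chosen after the data were seen. Where no cause is named below, the cause was not tested. The rRNA share kept its direction under each alternative, with ratios of 0.425 in mini-bulk and 0.341 in single cells over counts without mitochondrial genes. With rRNA left out of the total, the ratio of the mitochondrial mRNA share was 0.474 in mini-bulk and 0.42 in single cells, and that of nuclear long non-coding RNAs turned to 0.999 and 0.816. The lincRNA genes inside 18S rRNA stayed in this total, so these ratios still depend on them. They took 37.1% of all untreated and 17.4% of all DASHed mini-bulk counts. The small nuclear RNA ratio in single cells was 0.725 to 1.05 with 1 cell left out, turning to 1.05 without DASHed replicate 1 and 1.04 without untreated replicate 4, and turned to 1.03 with pairing as replicate block. Ratios of detected genes were 1.63 and 1.16 at a minimum of 5 counts and 2.17 and 1.32 at 10 in mini-bulk and single cells. They were 0.759 and 0.783 unthinned because of depth, and 1.06 and 0.935 with rRNA, but not the lincRNA genes inside 18S rRNA, left out.

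The 2997 mini-bulk calls (998 up, 1999 down) became 2178 (920, 1258) with at least 50 counts, 1490 (142, 1348) against 1.5-fold, 1860 (790, 1070) with the DESeq2 Wald test, 4924 (2252, 2672) with single-cell sums, 6856 (6718, 138) with totals alone and 1417 to 3450 with 1 library left out (205 to 1356 up, 1192 to 2094 down), where the lone library of an arm is assumed to vary like the other arm. GC correction gave 395 calls (174, 221), of which 274 were shared with the 2997, 269 in the same direction. Same-numbered mini-bulk libraries share only a number. Their deviations correlated at 0.42, a single value that the 2 pairs share, because each group has 2 libraries and is centred on its mean. Replicate number as a block gave 5403 calls (2359, 3044), or 1601 (805, 796) with GC correction. The number of lists past the threshold was 9, and 0 with an estimated correlation, 11 with fry, 10 with totals alone, 5 with GC correction, 4 with GC correction and block, and 7 to 11 with 1 library left out, not always the same lists. With totals alone the calls of snoRNA hosts (camera adjusted p = 0.148) and immediate-early genes (0.1) ended. Fry asks whether a list moves one way and not whether it differs from other genes, so it cannot end a camera call. Under fry, immediate-early genes and G2 and M phase genes (fry adjusted p = 0.056 each) and chaperones and proteasome (0.0582) did not pass. With GC correction and block the median of immediate-early and heat shock genes turned to −0.012. B2M turned to 0.17 and 0.16 and DST to 0.16 and 0.15 with GC correction without and with the block.

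Of single-cell lists, 13 lay outside 95% of random lists, 8 with GC correction (6 of them on the same side as before), 6 with GC correction and pairing as replicate block, 11 against genes of like expression and 10 to 14 with 1 cell left out. The translation factor median turned to 0.57 with median CPM, 0.47 with a pseudocount of 10, 0.77 at a minimum of 1 count, −0.10 to 0.11 with 1 cell left out (above 0 in 5 of 8 cases), 0.54 with pairing, 0.137 with pairing without genes at 0 in both cells (chosen after the data were seen), 0.06 with GC correction and 0.47 with GC correction and pairing. The G2 and M phase median turned to 0.021 with median CPM, 0.001 with a pseudocount of 10, 0.244 at a minimum of 1 count, 0.007 with pairing, 0.075 with GC correction and 0.283 with both, with no turn when a cell was left out or in pairs without genes at 0 in both cells. At a minimum of 1 count nuclear long non-coding RNAs turned to 0.14 and chaperone and proteasome genes to 0.20, and with GC correction and pairing to 0.16 and 0.21. Ribosome assembly factors turned to −0.23 at a minimum of 100 counts and −0.24 against genes of like expression, where ribosomal protein genes were at −0.15 and long coding genes at −0.22. Histones turned to −1.35 without DASHed replicate 1 and were at 2.87 without untreated replicate 1, settings that break the histone-rich pair, while the share ratio within pairs was 4.59 to 6.35. The fold correlation was 0.814 at 20 counts, 0.975 at 1000 and 0.759 to 0.885 with 1 library left out. Correlations within untreated groups were 0.839 and 0.584 thinned, 0.913 and 0.513 by rank, and 0.932 and 0.579 without rRNA, and within DASHed groups 0.876 and 0.504 by rank. Over 1487 values of named mini-bulk genes under the alternatives, 1289 kept direction and side of the threshold, 173 were no longer past it (67 with GC correction, 33 with 1 library left out), 21 newly passed and 4 turned, as given above. The call of the mitochondrial rRNAs ended with the mini-bulk block (adjusted p = 0.0684). Pairing or block turned no other list median, single-cell share ratio or named mini-bulk gene. Of named single-cell genes, the mean over pairs turned SNHG6 from −0.084 to 0.582, NDUFS5 from −0.284 to 0.391, HERC1 from −0.268 to 0.008, EPCAM from 0.179 to −0.086 and SNORD3A from 0.274 to −0.118. Without genes at 0 in both cells it was 0.183, −0.008, −0.391, −0.485 and −0.313 in that order, and RNU2-1 turned from 0.648 to −0.133. Depth limits genes with no counts in a group to bounds. Of 2-fold changes in mini-bulk, simulated without the lower rRNA share of DASHed libraries, 11.5% were recovered.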

Other observations

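The test of the lincRNA genes inside 18S rRNA was chosen after the result was seen, as was the GC correction. The tests on mitochondrial mRNAs and on depth and chance in the GC trend were planned before their results were seen.

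RF00100, the family name under which 7SK RNA, a regulator of transcription elongation, is counted, took 1.36% ± 0.158 of mini-bulk counts after depletion and 0.132% ± 0.00395 without it (SD, n = 2 each), a ratio of 10.3. In single cells it took 0.758 to 1.75% against 0.107 to 0.24%, a ratio of means of 6.97. The ratio of 28S to 18S rRNA counts was 0.445 and 0.473 in DASHed and 0.589 and 0.653 in untreated mini-bulk libraries. It was 1.21 to 1.45 in DASHed and 1.82 to 2.04 in untreated single cells. Its 18S counts are those of RNA18S4 alone. The lincRNA genes inside 18S rRNA, left out here, took 37.1% of untreated mini-bulk counts, against 22.5% for RNA18S4. In untreated single cells they took 26.3% against 14.9%. If they hold 18S reads, the ratios of 28S to 18S rRNA given here are too high. The ratios and the RF00100 shares were singled out after they were seen.

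Mini-bulk fold changes followed transcript GC content (rho = 0.789). A difference in total counts alone is argued against by thinning all 4 libraries to equal totals, after which rho was 0.734. Of these totals, rRNA and the lincRNA genes inside 18S rRNA took 40.4% in DASHed and 84.0% in untreated libraries. Depth over the other genes thus stayed unequal, so the thinning cannot decide on that depth. Chance differences in GC recovery are argued against by pairs of libraries within a group, which reached at most 0.132. Pairs across treatments had 0.154 to 0.505 in single cells and 0.672 to 0.756 in mini-bulk. The correction narrowed the log2 fold changes of all 10083 tested genes from an SD of 1.32 to 0.87. It took the 998 genes that rose without it, a set chosen by that call, from a median of 0.93 (SD 0.47) to 0.31 (SD 0.56) and the 1999 that fell from −2.13 (SD 0.99) to −0.78 (SD 1.04). Medians of lists fixed before the data were examined, whose calls ended, shrank from −1.30 (SD 1.15) to −0.15 (SD 0.52) for G2 and M phase genes, −1.18 (SD 1.14) to −0.20 (SD 0.83) for chaperones and proteasome, −1.68 (SD 0.97) to −0.38 (SD 0.72) for nuclear long non-coding RNAs, −1.41 (SD 1.01) to −0.35 (SD 0.85) for snoRNA hosts and 0.65 (SD 0.86) to 0.01 (SD 0.52) for immediate-early genes. A step that treats fragments by GC content in the DASHed libraries, such as further amplification, may be the source and stays open, since the labels describe no such step. No biological explanation was tested.

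Mitochondrial mRNAs fell beyond that trend. Their median of −2.81 lay below 10000 sets of nuclear genes matched on GC content (−1.92 to −0.60, median −1.28), which argues against GC content as the whole cause. GC correction left −1.63 (SD 0.64, before it −2.81, SD 0.93). The median also lay below sets matched on transcript length (−0.93 to 0.80). That length is the median over a gene's annotated transcripts and need not be that of the expressed one, so these sets cannot decide on length. Cutting by guides that match mitochondrial rRNA, or loss of fragments that join it to neighbouring transcripts, may contribute and stays open, because guide sequences were not used here. No biological explanation was tested.

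The lincRNA genes inside 18S rRNA fell about as far as 18S rRNA in the mini-bulk libraries. The log2 fold changes of the 3 identical ones, FP236383.2, FP236383.3 and FP671120.3, differed from that of 18S rRNA by at most 0.069, and FP671120.4 fell by 3.14 (SE 0.21). The 3 identical genes hold equal counts, so they are not separate evidence. 18S reads assigned to these genes would fall this way, a hypothesis found and tested on the same data. Transcripts of the lincRNA genes also lie inside 18S sequence, which the depletion cuts, so they could fall alike. The equal fall therefore cannot tell these sources apart. In single cells the share ratio of FP671120.4 was 0.605 (0.506 to 0.67 over pairs) against 0.436 (0.354 to 0.5) for 18S rRNA, so this gene was lowered less there, while that of FP236383.2, one of the identical genes, was 0.456 (0.377 to 0.513). What stays open is whether any of these counts are transcripts of the lincRNA genes themselves, since the handling of strand is not given in the sources used here. No biological explanation was tested.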
